A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

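Gene expression was measured in fission yeast (Schizosaccharomyces pombe) on 2 spotted DNA arrays, each hybridised with labelled cDNA from a tup11 tup12 double mutant and from a wild-type strain. Per the labels, the mutant carried Cy3 and the wild type Cy5 on array 1, and the dyes were swapped on array 2. Per the series design text, the cultures grew in rich medium to logarithmic phase and each array received its own RNA preparation, so the arrays were treated as 2 replicates of the same comparison. A growth temperature of 30 degrees was stated for array 1 alone. Protocols for growth, extraction and labelling were given by the labels as a literature reference, and the image software and scanner settings were not given in the sources used here.

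The deposited scanner tables held spot intensities on a linear scale, per the file headers, as means and medians of foreground and local background for each of 2 channels, with a saturation value of 65535. They also held a quality code of 0, 2 or 3 for each spot and channel, per the file headers, whose meaning was not given in the sources used here. Spots with code 2 were dim, with median signals of 13.5 to 1507 across channels, and spots with code 3 were bright, with medians of 6108 to 21996. The authors also deposited 1 table of normalised log ratios, made by Lowess per array according to the series design text. Set against the scanner signals, the authors' deposited values behaved as log10 ratios of the first over the second channel of each array, with correlations of 0.94 over 9033 spots on array 1 and 0.80 over 9172 spots on array 2. The medians of the deposited log10 columns were -0.01 and 0.02, and 159 and 108 spots stood at a floor of -2. Scale and centring were thus read from the values, and the direction in terms of strains was unstated.

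The column headers named neither the dye nor the strain of a channel. The mean local background of the first channel was 1.80 on array 1 and 753 on array 2, and that of the second channel was 408 and 12.5. The dyes had therefore changed places between the channel columns of the arrays, so the first channel held RNA of the same strain on both. The authors' values placed the first channel in the numerator and the titles named the mutant first. The first channel was accordingly read as the mutant on both arrays, which is likely but not stated, and every signed value rests on it.

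Each array carried 11520 spots, printed as 2 sets of 5760 spots. Control or unnamed spots took 1548 positions, among them 1086 empty ones, and 4956 gene features remained. Names were matched to the ASM294v3 gene table by systematic name (3467 features), symbol (943) or synonym (366), and 180 features kept the name of the array. The table was used for names and gene order only. Features that shared a gene with another feature (48) were kept apart.

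Median signals and median backgrounds were corrected with normexp (offset 50) and normalised with 1 loess curve per array, in which control spots and spots with code 3 had weight 0. Spots with code 3 in either channel were then left out, 905 on array 1 and 765 on array 2, and the spots of a feature were averaged. A value on both arrays was required, which left 4813 features for testing and removed 143. Log2 ratios of mutant over wild type were fitted with limma (version 3.58.1, in R 4.3.3, with statmod 1.5.0) by lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Reading both arrays as mutant over wild type is the same as giving the arrays opposite signs in a dye-based design. With 1 residual degree of freedom a dye term was not added. The prior contributed 8.55 degrees of freedom to a total of 9.55, so most of the error came from the spread pooled over genes.

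A spot was taken as well above background when its background-subtracted signal exceeded the 95th percentile of 96 spots of bacterial control DNA (aceF and kdtA) in the same channel, a rule chosen after the signals had been seen. Spots of a further bacterial gene, tufA, were brighter and were not used for it; their mean signal itself passed in 3 of the 4 channels, at 609, 2120 and 490 against 442, 1659 and 488, so passing does not exclude unspecific signal. Between 70.1% and 79.7% of gene spots passed it. Where a gene did not pass in the dimmer strain on either array, its fold is given as a bound, with the dim channel at its own signal or at the lowest normalised signal among genes that passed, whichever was higher on each array; where its own was higher, bound and fitted fold are the same. Per-channel values came from loess followed by Aquantile normalisation. The number of arrays limits the precision of all values.

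The test was checked on simulated values for 4813 genes with the fitted spread, in which 200 genes were changed. It recovered 67.2% of genes changed by 1 on the log2 scale, 100% of those changed by 2 and 100% of those changed by 3, with 3 false calls among 181. The simulated values were independent and followed the spread that the fit assumes, without errors of dye, saturation or normalisation. The check therefore does not give the rate of false calls in the real data.

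The 23 gene lists, the tests of genes and lists between the strains and the rule for named genes were fixed before the data were examined. The lists were tested with camera in limma with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The named genes were tup11, tup12 and ssn6, then the 12 highest and 12 lowest means among called genes of like sign on both arrays, then up to 4 members with the largest absolute mean of each list that passed or held a called gene, 84 features in all. Other genes named in the text were chosen after their values were seen. Alternatives covered background correction, normalisation, the authors' values, filters on dim and coded spots, scaling, averaging over spots, variance moderation, thresholds, the fit on duplicate spots, and the omission of either array. Mean signals, the omission of spots with code 2 in both channels, and the omission of 239 features with a saturated spot were added after the data had been seen.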

Results

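The series compared gene expression in a fission yeast double mutant of tup11 and tup12, which encode a pair of related transcriptional corepressors, with that in a wild-type strain. The labels mark the mutant with a D, read here as deletion of both genes, and the question was which genes differ in expression between the strains. Both strains were grown in rich medium and compared directly on 2 dye-swapped arrays, each with its own RNA preparation, so n = 2 throughout. Median gene signals ranged from 1341 to 4239 across the 4 array channels. The reading of the first channel as the mutant is likely but not stated in the file headers, and every higher or lower given here rests on it. Read the other way, every sign would turn.

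Values are means of log2 mutant over wild type ± SD of the 2 arrays. A feature named tup1 was 4.32-fold lower in the mutant, at -2.11 ± 0.36 (n = 2, limma adjusted p = 0.000446). It matched no gene in the ASM294v3 table, so the corepressor gene it reads is not settled. The feature of tup11 gave 0.95 on array 1 and -0.11 on array 2 and was not called (adjusted p = 0.489), although a probe outside a deleted part checks nothing. Both features were well above background in both strains on both arrays, so neither showed a complete loss of signal in the channel read as the mutant, and deletion was not verified here. No feature was analysed under the name tup12. The gene of the partner corepressor Ssn6 stood at -0.19 ± 0.13 (adjusted p = 0.724).

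Expression of 161 of 4813 genes differed between the strains, with 114 higher and 47 lower in the mutant, or 47 higher and 114 lower if the channels were read the other way. The largest increases were in cta3, which encodes a cation-transporting ATPase, and inv1, which encodes the secreted invertase. The gene cta3 rose 51.4-fold (5.68 ± 1.35) and inv1 rose 50.1-fold (5.65 ± 0.04), and in both the wild-type signal was well above background on 1 of the 2 arrays. The fold of cta3 was 26.5 on array 1 and 99.5 on array 2. Over the 13 other settings that gave cta3 a value, its fold ranged from 15.2 with the authors' deposited values to 116 with a normexp offset of 0. That of inv1, over 14 other settings, ranged from 31.5 with mean signals, a setting added after the data were seen, to 85.6 with plain background subtraction. The SD of its 2 arrays therefore understates the uncertainty of its fold. At least 1 spot of inv1 was also saturated, which compresses a ratio. Among called genes, 8 had a saturated spot, among them hsp16 and erg1, described below. Next came SPCC1739.08c (29.1-fold, wild type well above background on 1 array), the iron permease gene fip1 (19.5-fold, 4.28 ± 0.27) and the glucose dehydrogenase gene gcd1 (14.6-fold, wild type well above background on 1 array). The glycerol dehydrogenase gene gld1 rose 12.5-fold, gut2, which encodes a glycerol-3-phosphate dehydrogenase, 8.68-fold, and mei2, which encodes an RNA-binding protein needed for entry into meiosis, 6.91-fold. In the remaining genes of the 12 highest the wild type was not well above background on either array. These were frp1 (at least 8.47-fold), SPCC794.04c (at least 7.36-fold), nrg1 (at least 4.57-fold) and isp3 (at least 4.08-fold). Such bounds allow for a dim channel and not for the spread of the arrays. For frp1 and SPCC794.04c they equal the fitted folds, whose 95% intervals start at 6.22 and 5.09.

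Decreases were smaller, with a median fold of 2.10 among lower genes against 2.56 among higher ones. The lowest means were those of gdt1 (at least 4.83-fold lower, mutant not well above background), SPAC3G6.05 (4.91-fold lower, -2.30 ± 0.38) and the tup1 feature. The tRNA methyltransferase gene trm44 was at least 3.50-fold lower and SPCC569.01c at least 3.12-fold lower. The biotin transporter gene vht1 was 3.29-fold lower (-1.72 ± 0.34), cbm1 3.28-fold lower (-1.71 ± 0.13) and SPBC1271.07c 3.10-fold lower. SPAC11D3.02c (2.78-fold, mutant well above background on 1 array), SPCC70.08c (2.61-fold), the tropomyosin gene cdc8 (2.44-fold) and SPAC977.12 (2.42-fold) completed the 12 lowest.

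**Figure D1:**
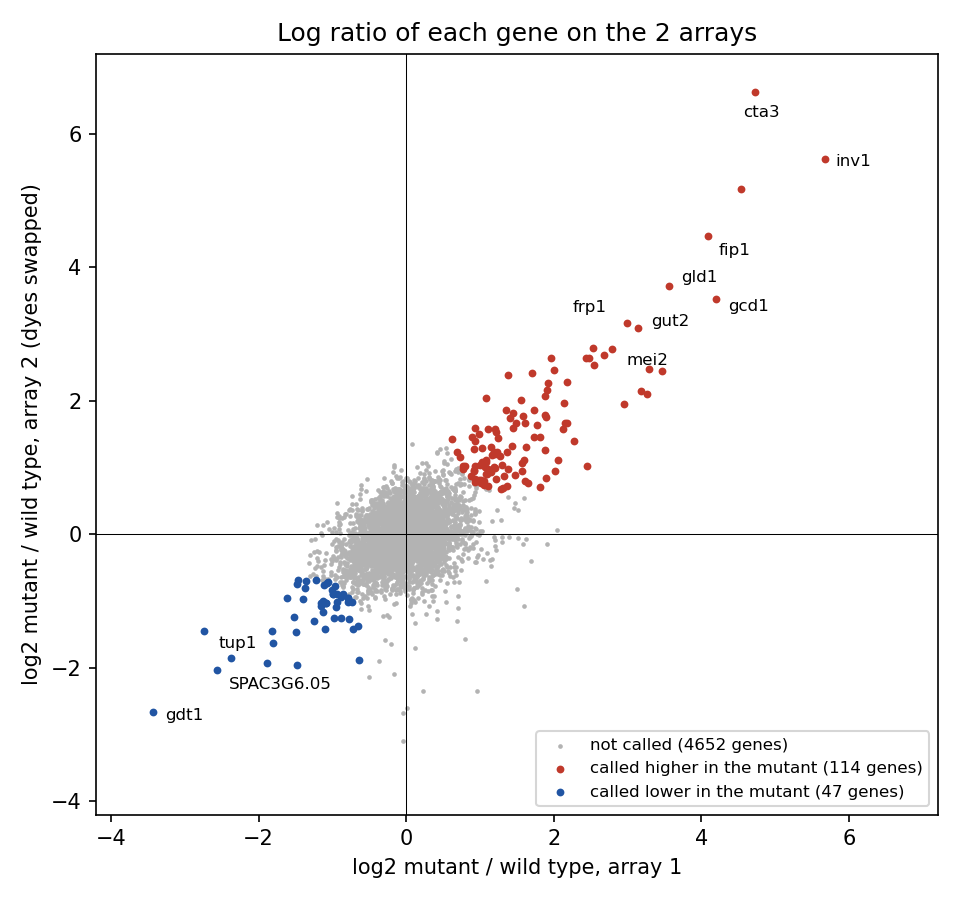
Log2 ratio of mutant over wild type for each of 4813 genes on array 1 (horizontal) and on dye-swapped array 2 (vertical); each point is a gene, with the 114 genes called higher in red, the 47 called lower in blue and the rest in grey. The called genes lie along the diagonal and have the same sign on both arrays.

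Without a test, 73 genes were at least 2-fold higher and 18 at least 2-fold lower in the mutant on both arrays, while 1 gene reached 2-fold in opposite directions. All 91 genes with like direction were among the 161 called by limma. Across genes, which are not independent replicates, the log ratios of the arrays correlated at r = 0.55 (Spearman 0.34). The count of called genes depended on normalisation and moved from 161 to 365 with print-tip loess (195 higher and 170 lower) and to 38 with median centring (33 higher and 5 lower). With the authors' deposited values it was 53, and cta3 then missed the threshold (adjusted p = 0.0579). Of 53 called genes named by rule, 33 lost the call in at least 1 setting, rps1702 in the most (4).

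Of the 23 gene lists, 10 passed camera at an adjusted p of 0.05; with an estimated correlation none did, and each of these 10 lists then had an adjusted p = 0.66. The test fry, which asks whether a list's genes move one way, passed 1 list, ribosome biogenesis (adjusted p = 0.0264). Fry and the estimated correlation rest on 1 residual degree of freedom, so passing or failing them does not rank the lists. In ribosome biogenesis, 15 of 21 members were lower on both arrays, with a median of -0.34. In iron acquisition, which did not pass fry, 12 of 12 were higher on both, with a median of 1.30.

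Genes for iron acquisition had the lowest p-value in camera at the preset correlation, and did not pass fry (adjusted p = 0.0842). Of 12 measured members, 7 rose, none fell and 5 did not pass, and adjusted over the list alone 9 rose. The median log2 ratio was 1.30 (camera adjusted p = 1.1e-15, adjusted p = 0.66 with an estimated correlation). Besides fip1 and frp1, which encodes a ferric reductase, the siderophore transporter gene str3 rose 5.90-fold (2.56 ± 0.11) and the siderophore synthesis gene sib2 rose 5.83-fold (2.54 ± 0.0013). The genes str1 and sib1 rose 5.49-fold and 3.10-fold, and shu1 rose at least 1.36-fold, with a wild type not well above background. The mutant signal of shu1 was well above background on 1 of the 2 arrays. The ferroxidase gene fio1 stood at 0.30 ± 0.18 (adjusted p = 0.533) and was not called.

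Among 14 glucose-repressed genes 8 rose, 1 fell and 5 did not pass, and adjusted over the list alone 10 rose and 1 fell. Their median was 1.07 (camera adjusted p = 4.4e-12, adjusted p = 0.66 with an estimated correlation). Without inv1, the member with a saturated spot, 7 rose and the median was 0.94. Besides inv1, gld1 and gut2, the alpha-glucosidase gene agl1 rose 4.94-fold (2.30 ± 0.48), the dihydroxyacetone kinase genes dak1 and dak2 rose 2.32-fold and 2.30-fold, and the transcription factor gene rsv1 rose 1.92-fold. The member that fell was fbp1, the fructose-1,6-bisphosphatase gene, at -1.02 ± 0.10 (at least 1.36-fold lower, adjusted p = 0.0218). Its mutant signal was not well above background on either array, and with the authors' deposited values its mean was 0.23. Of 6 hexose transporter genes, ght4 (at least 1.82-fold) and ght1 (at least 2.60-fold) rose and 4 did not pass. The mutant signal of ght4 was well above background on 1 array. The bound of ght1 equals its fitted fold, whose 95% interval starts at 1.91. The genes ght3, ght4 and ght6 also belonged to the glucose-repressed list, so these lists are not independent. Adjusted over the list alone 4 of the hexose transporter genes rose and 1 fell. Their median was 0.81 (camera adjusted p = 0.000659, adjusted p = 0.66 with an estimated correlation), and ght6 and ght3 stood at 0.83 ± 0.15 and 0.78 ± 0.09 without passing over all genes.

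Genes of mating and pheromone response had a median of 0.46 (camera adjusted p = 2.4e-07, adjusted p = 0.66 with an estimated correlation), and 6 of 19 rose, 8 adjusted over the list alone. These were mei2, the G-protein signalling regulator gene rgs1 (3.19-fold, 1.68 ± 0.13), the M-factor exporter gene mam1 (3.12-fold), gpa1, which encodes a G-protein alpha subunit (2.34-fold), the transcription factor gene ste11 (1.92-fold) and mam4 (1.83-fold). In meiosis and sporulation isp3 alone rose among 27 members, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.221). Of these 27, 9 were not well above background in either strain on either array. For nitrogen starvation and amino acid uptake 5 of 14 genes rose, also 5 adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.000418, adjusted p = 0.66 with an estimated correlation). They were isp4 (at least 3.05-fold), per1 (3.26-fold), isp6 (2.45-fold), the proline permease gene put4 (2.27-fold) and isp5 (2.01-fold).

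In the core stress response 5 of 26 genes rose and 21 did not pass; adjusted over the list alone 7 rose and 1 fell. The median was 0.17 (camera adjusted p = 0.0017, adjusted p = 0.66 with an estimated correlation). The genes were cta3, the small heat-shock protein gene hsp16 (3.94-fold, 1.98 ± 0.14), rds1 (3.45-fold), hsp9 (2.40-fold) and lsd90 (1.99-fold). Among heat shock chaperones hsp16 alone rose of 13, and the list's median of -0.07 and mean of 0.06 differed in sign (camera adjusted p = 0.956). Adjusted over that list alone 1 rose and 2 fell, the latter sti1 (-0.92 ± 0.43) and wos2 (-0.84 ± 0.09).

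Of 11 features for flocculins and other adhesins, 2 rose, also 2 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.0419, adjusted p = 0.66 with an estimated correlation). The features of the flocculin gene gsf2 disagreed, 1 rising 6.34-fold (2.66 ± 0.18) and the other at -0.42 ± 0.25 (adjusted p = 0.366), and pfl8 rose 2.12-fold. In glycolysis and fermentation the pyruvate decarboxylase gene pdc201 rose 4.11-fold (2.04 ± 0.18, wild type well above background on 1 array) while 9 other genes did not pass, with 1 adjusted over the list alone. The list median was 0.17 (camera adjusted p = 0.0438, adjusted p = 0.66 with an estimated correlation). Of its 10 genes 7 had a saturated spot, which compresses a ratio, and the 3 others had a median of 0.49. The saturated gpd3 and gpm1 both stood at 0.49 on array 1 and -0.19 on array 2, values shared by many saturated features. The median of the full list therefore partly reflects saturation.

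**Figure D2:**
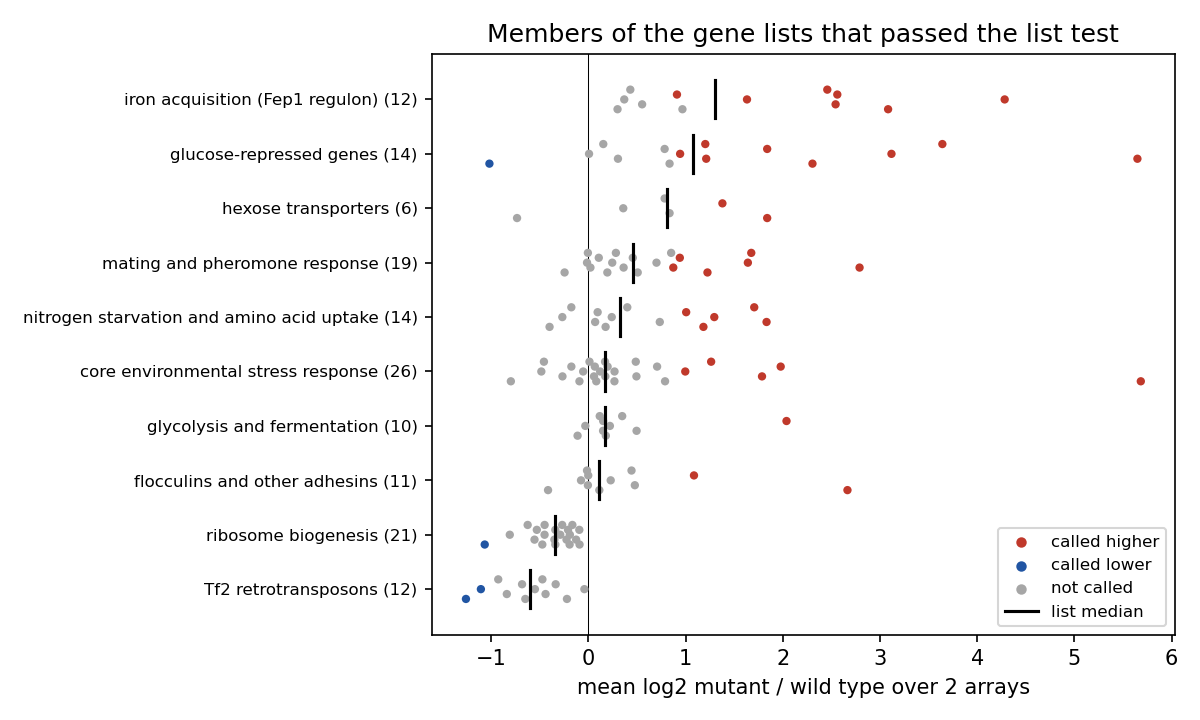
Mean log2 ratio of mutant over wild type on 2 arrays for each measured member of the 10 gene lists that passed camera, with the number of members in parentheses; points are genes, coloured by call, shifted vertically for legibility, and the black line is the list median. Iron acquisition (median 1.30) and glucose-repressed genes (1.07) lie highest, and Tf2 retrotransposons (-0.60) lowest.

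Tf2 retrotransposons and ribosome biogenesis genes passed in the lower direction. Of 12 Tf2 features 2 fell, 6 adjusted over the list alone, with a median of -0.60 (camera adjusted p = 8.7e-07, adjusted p = 0.66 with an estimated correlation). Tf2-10 was at least 1.70-fold lower and 1 feature of Tf2-8 was 2.15-fold lower (-1.11 ± 0.52), whereas Tf2-1 and Tf2-3, at -0.93 ± 0.48 and -0.84 ± 0.40, did not pass. Tf2 copies are close in sequence, so a feature can read several of them. Of 21 ribosome biogenesis genes the snoRNP protein gene nop56 fell (2.10-fold lower, -1.07 ± 0.09) and 20 did not pass; adjusted over the list alone 2 fell, the second being nhp2 (-0.81 ± 0.27). The median was -0.34 (camera adjusted p = 2.8e-05, adjusted p = 0.66 with an estimated correlation).

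The remaining 13 lists did not pass camera. Among 13 cation transport genes cta3 and pmc1 (2.36-fold) rose and the zinc transporter gene zrt1 fell (2.10-fold lower), with the same calls adjusted over the list alone (camera adjusted p = 0.241). Without 2 features that had a saturated spot the list passed (camera adjusted p = 0.0299, adjusted p = 0.536 with an estimated correlation). Of 89 subtelomeric genes 7 rose and 7 fell, 10 and 8 adjusted over the list alone (camera adjusted p = 0.413). Of the 89, 34 were not well above background in either strain on either array. Camera asks about a shift in a single direction, so changes in both directions can cancel in it. Over all tested genes 3.3% were called, and whether subtelomeric genes were called more often was not tested. Of 113 ribosomal protein genes 4 fell, also 4 adjusted over the list alone, among them rpl42 (2.13-fold lower), rps1702 and rpl39 (each 1.92-fold lower). The median of that list was 0.11 and its mean -0.04, with opposite signs (camera adjusted p = 0.586). However, 86 of the 113 had a saturated spot, which compresses a ratio. Many of the 86 stood near the same values, as rps1801 and rpl802 did at 0.49 on array 1 and -0.19 on array 2. The positive median of the full list therefore partly reflects saturation. The 27 genes without a saturated spot had a median of -0.37 and 3 of them fell (camera adjusted p = 6.0e-05, adjusted p = 0.536 with an estimated correlation), in a check added after the data were seen. The citrate synthase gene cit1 rose 1.97-fold among 32 genes of the citric acid cycle and respiration (camera adjusted p = 0.238), as 1 gene adjusted over the list alone. The squalene epoxidase gene erg1 rose 2.37-fold among 19 ergosterol genes, of which 2 rose adjusted over the list alone; that list's median of -0.10 and mean of 0.03 differed in sign (camera adjusted p = 0.956). Of 7 marker loci ura4 rose (at least 2.0-fold, with 2.45 on array 1 and 1.02 on array 2). Its mutant signal was well above background on 1 array. Adjusted over the list alone 1 rose and 1, lys1 (-0.64 ± 0.10), fell (camera adjusted p = 0.646). That list's median of -0.10 and mean of 0.04 differed in sign, and 4 of the loci had a saturated spot.

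No member of the other lists was called over all genes. Their medians were 0.23 for 6 thiamine-repressed genes, of which 1 rose adjusted over the list alone (camera adjusted p = 0.194), and -0.07 for 24 wtf genes (camera adjusted p = 0.586). They were 0.19 for 3 phosphate genes and 0.10 for 8 histone genes, 6 of them with a saturated spot (camera adjusted p = 0.693 for both), and 0.01 for 9 corepressor and partner genes (camera adjusted p = 0.956). Adjusted over the list alone, 0 members of these last 4 lists were called with limma. Of the 24 wtf genes, 10 were not well above background in either strain on either array.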

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

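The dye test and both fbp1 tests were chosen after the results they bear on had been seen; the Tf2 tests were set before theirs were run. Of the control and unnamed features outside the gene comparison, none was at least 2-fold higher in the mutant on both arrays with a signal well above background. The nearest, a control well above background in both strains, stood at 0.90 on array 1 and 1.41 on array 2. Spots of 3 foreign genes differed between the arrays: luciferase was at 0.32 and -1.47, Gfp at 0.46 and -1.51 and Gst at 0.20 and -1.49.

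The calls between the strains could in principle come from dye bias that survived normalisation. Dye bias would turn its sign with the dyes, and 1 gene was 2-fold in opposite directions on the arrays against 91 in the same direction. Dye bias as the whole source of the large changes is therefore argued against. Bias that follows the spot and not the dye stays open, as does the strain difference itself.

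The decrease of fbp1 ran against the 8 glucose-repressed genes that rose. Its signal was near background: 1 of the 4 measurements, 2 strains on 2 arrays, lay above the level of bacterial control DNA. The same count held for shu1, ght4 and ura4, which rose. In 3 of 12 other settings the call of fbp1 or its sign on an array was lost. Plain background subtraction gave -1.20 and -2.60 on the arrays (limma adjusted p = 0.105), and median centring -2.07 and -0.46 (limma adjusted p = 0.983). Their means of -1.9 and -1.27 were larger in size than -1.02, with a wider spread. The authors' values gave -0.93 and 1.40 (limma adjusted p = 0.892). Over the 12 settings the adjusted p ranged from 0.000202 to 0.983 and the mean turned in 1, so an effect of the processing stays open. A lower fbp1 level in the mutant stays open and may be no more than a dim signal.

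The lower Tf2 features may reflect bias of dim or bright spots, or a signal shared among copies. Their median of -0.60 lay at percentile 0 of 10000 random gene lists matched on average intensity, whose central 95% ran from -0.23 to 0.17. After loess the Tf2 features were thus lower than other genes of like intensity. Loess had already centred the log ratios on that intensity, so the matched lists lie near 0 by construction. The test therefore cannot decide on intensity bias. It also drew separate genes, while Tf2 features can share signal, so the percentile is overstated. The 12 features differed among themselves by more than the error of the fit (chi-square 32.4, p = 0.00066), which argues against a single signal read alike by all of them. The chi-square test took the fitted errors as exact, so its p-value is too small. In some features, as Tf2-10 and Tf2-1, the mutant was not well above background on either array, so ratios could differ although the signal was shared. Intensity bias, a partly shared signal, a shared signal read unequally by dim features, a different number of Tf2 copies in the strains and lower Tf2 expression in the mutant stay open. The latter 2 were not tested.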

How the results depend on the processing

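Mean signals and the omission of spots with code 2 in both channels or of saturated features were chosen after seeing the data. Against 161 called genes, the count rose to 328 without background correction, 365 with print-tip loess, 260 without dim spots, 252 with code 3 spots kept, 273 with an intensity trend in eBayes, 279 in the fit on duplicate spots, 366 with mean signals, 260 without spots of code 2 in both channels, and 251 at an adjusted p threshold of 0.10. It was 60 with plain subtraction, 38 with median centring and 53 with the authors' deposited values. Of these smaller sets 59, 38 and 52 genes were among the 161, and the 365 held all 161. The share of higher genes ran from 52.7% with mean signals to 86.8% with median centring. The cause was not tested, apart from the looser threshold. In the fit on duplicate spots the estimated correlation between them was -0.0054, so spots of the same array counted almost as separate replicates. Its count of 279 thus rests on spots and not on the 2 arrays as replicates.

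The number of genes 2-fold on both arrays stayed within 1.5 times of 91 in every setting that kept the fold minimum and both arrays; it was 266 at 1.5-fold, where the looser minimum is the cause, and 165–195 on single arrays, where agreement of the arrays is not asked for. Leaving out an array leaves no test, so no count of called genes or passing lists was made. Of the lists, 8 to 13 passed in the other settings, but 1 passed with fry and 0 with an estimated correlation. Those last tests rest on 1 residual degree of freedom. Apart from these set tests, flocculins lost the call in 3 of 15 settings and glycolysis in 5, and the other 8 lists kept direction and call in all 15. Of 786 values of 53 called named genes, 716 kept direction and call, 70 lost the call and 0 reversed. Genes that were not called reversed as follows: ade6 was 0.048 with median centring, and pyk1 was -0.025 with the authors' values and -0.0053 with code 3 spots kept. No paired analysis was possible because each array's log ratio already is a paired difference of the strains, to which no further block can be added.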

Other observations

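Tests on neighbouring genes were chosen after the called genes had been seen. The genes in this paragraph belong to none of the fixed lists and were likewise picked after their values were seen, from 103 such called genes, 72 higher and 31 lower in the mutant. No theme among them was tested. The gene isu1, for the iron-sulphur cluster scaffold, rose 2.54-fold, hem15, for ferrochelatase, 2.15-fold, and mrs3, for a mitochondrial iron carrier, 2.03-fold. The glutamate dehydrogenase genes went apart, with gdh1 at 5.80-fold higher (2.54 ± 0.14) and gdh2 at 2.16-fold lower (-1.11 ± 0.19). Others that rose were ste7 (at least 3.96-fold), the meiotic cyclin gene rem1 (at least 2.49-fold), gsf1 (3.04-fold) and mbx2 (1.84-fold). So did cgs1, for the regulatory subunit of protein kinase A (1.94-fold), the gluconokinase gene idn1 (3.60-fold) and urg1 (3.56-fold).

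Called genes of like direction often lay next to each other. Of 4616 measured genes placed in chromosome order by the ASM294v3 table, 151 were called, and they formed 13 neighbouring pairs of like direction, 12 higher and 1 lower. Random reassignment of the calls gave a median of 3 pairs and at most 11 in 10000 draws (permutation p = 0.0001, one-sided, the smallest these draws can give). Pairs included lmb1 with gdh1, sib1 with sib2, shu1 with str3, ght4 with frp1, and isp3 with pfl8. After print-tip loess, which removes bias between print blocks, 25 pairs were found (permutation p = 0.0009). The draws gave a median of 13 and at most 28, so the relative excess was smaller. All 13 earlier pairs were among the 25, so this excess is not a separate result. Their persistence argues against bias between print blocks as the whole cause. Both tests were chosen after the calls had been seen, so neither p-value excludes chance. The hypothesis that neighbouring genes change together is in line with these counts, and no mechanism was tested. Overlapping or similar sequences of neighbouring features could not be examined, because spot sequences were not used here.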
